A study of Homo sapiens with 15 samples.

How the data were processed

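RNA was sequenced from H1299 cells kept for 12 h in 5 media, with 3 libraries per medium and 15 in all. The deposited table holds raw counts per Ensembl gene for 58395 genes, with no normalization. The submitters' processing notes name HISAT2 2.1.0, featureCounts, Subread 1.5.1 and GRCh38.p12 without saying how they were used, and the strand setting and the treatment of reads that map to several places are not given in the sources used here. The labels describe poly(A) selection and a stranded kit. Gene names, positions and types came from GENCODE 29 (Ensembl 94), which holds 58275 of the gene IDs and lacks 120.

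Library totals ran from 14914127 to 19938691 counts. A floor of 3 counts therefore lay between 0.15 and 0.201 CPM, and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Across 15 pairs of libraries from the same medium the chi-square per degree of freedom was 1.231 to 2.463 (median 1.382), and 0 pairs were identical. Labels give each library a replicate number but do not say that equal numbers share a day. Residual correlations between libraries with equal numbers (30 pairs, median -0.005) lay near those between different numbers (60 pairs, median -0.002), and 7 of 15 libraries correlated best with their own number, so libraries were not paired. Principal components used log2(CPM + 1) of genes with at least 10 CPM in every library, with CPM relative to library totals without TMM scaling.

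Counts were scaled by TMM and tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, in a single fit of the 15 libraries with a mean per medium, 10 residual degrees of freedom and robust estimation. The filterByExpr filter kept 16889 genes. The common biological coefficient of variation was 0.0221. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes of a comparison, and all tests were two-sided. The 7 comparisons of media and the interaction between glucose and glutamine were fixed before the data were examined, as were the gene lists and the rule for naming genes.

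Gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, and again with a correlation estimated for each list. Of 37 lists, 34 had at least 3 measured members. The fatty acid and cholesterol synthesis lists were the primary ones, because the study was known to concern SREBP and lipid synthesis. That choice was therefore not blind to the subject of the study. The lists of fibroblast, endothelial and leukocyte markers held too few measured genes to be tested. Of their genes COL1A1, PDGFRB, ENG and CORO1A alone passed the low-count filter, with at most 31, 17, 314 and 94 counts in a library. Median and mean log2 changes and the direction of the test had the same sign for every list called.

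Genes were named by a fixed rule. In each comparison these were the 6 largest rises and the 6 largest falls among called genes with a symbol, a mean of at least 5 CPM and no overlap between the libraries of both groups, which chance gives for 10% of genes in groups of 3. To these came up to 4 members of each described list in its main direction and up to 2 in the other, chosen by the smallest p, members that did not pass, named with their values, and a panel of 21 genes of lipid synthesis, glucose response and amino acid stress. The overlap condition was not used for the interaction.

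Alternatives tried were DESeq2 size factors, library totals alone, no low-count filter, at least 1 CPM in 3 libraries, the Wald test of DESeq2 1.42.0 (whose dispersion trend used a local fit), a fit of the compared groups alone, a term for the replicate number, and leaving out each library in turn. After the data were seen, a test against a 1.2-fold change and a fit without 3 libraries that held many low-count genes were added. The steps were tested on simulated data shaped like the addition of NH4Cl to glucose. There 29 of 50 genes changed 1.2-fold were called, 37 of 50 at 1.5-fold, 47 of 50 at 2-fold and 49 of 50 at 4-fold, while 12 of 16495 unchanged genes were called, 6.9% of the calls. A list raised 1.5-fold was called and 0 of the other lists were, by camera of limma. The simulated genes varied independently, so this does not show how often lists with correlated members are called falsely. Some single genes that the naming rule covers are not reported here.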

Results

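Gene expression was measured in H1299, an established human line of non-small cell lung carcinoma, after 12 h in serum-free RPMI medium that held 5 mM glucose, 4 mM glutamine, both, neither, or 5 mM glucose with 4 mM NH4Cl, a salt that supplies ammonium. Each of the 5 media had 3 libraries of poly(A) RNA, 15 in all, with 14914127 to 19938691 counted reads per library. The labels describe triplicate cells and give no day or batch, so p-values measure only the spread between these samples, which may be technical. Levels below are means ± SD of 3 libraries in CPM, the counts of a gene relative to the TMM-scaled total of its library (n = 3 in every medium), and log2 changes carry the standard error (SE) of the fit. The libraries of each medium lay together on the principal components, of which the first held 61.3% of the variance and set the medium with neither nutrient apart from the rest. The components used library totals without TMM scaling. The TMM factors of 0.793 with neither nutrient (1.006 to 1.086 in the other media) can therefore add to the first component. The second held 20.1% and set apart the medium with both, and the third held 14.6% and set apart the medium with glutamine alone. Glucose with and without NH4Cl lay on opposite sides of the fourth, which held 2.2%. They also separated on the second, at 4.19 to 4.49 with NH4Cl and 11.2 to 11.5 without. The medium with both nutrients lay there at -29.6 to -29.2. On the first the separation was smaller, at -23.1 to -21.6 with NH4Cl and -25.6 to -25.1 without.

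**Figure D1:**
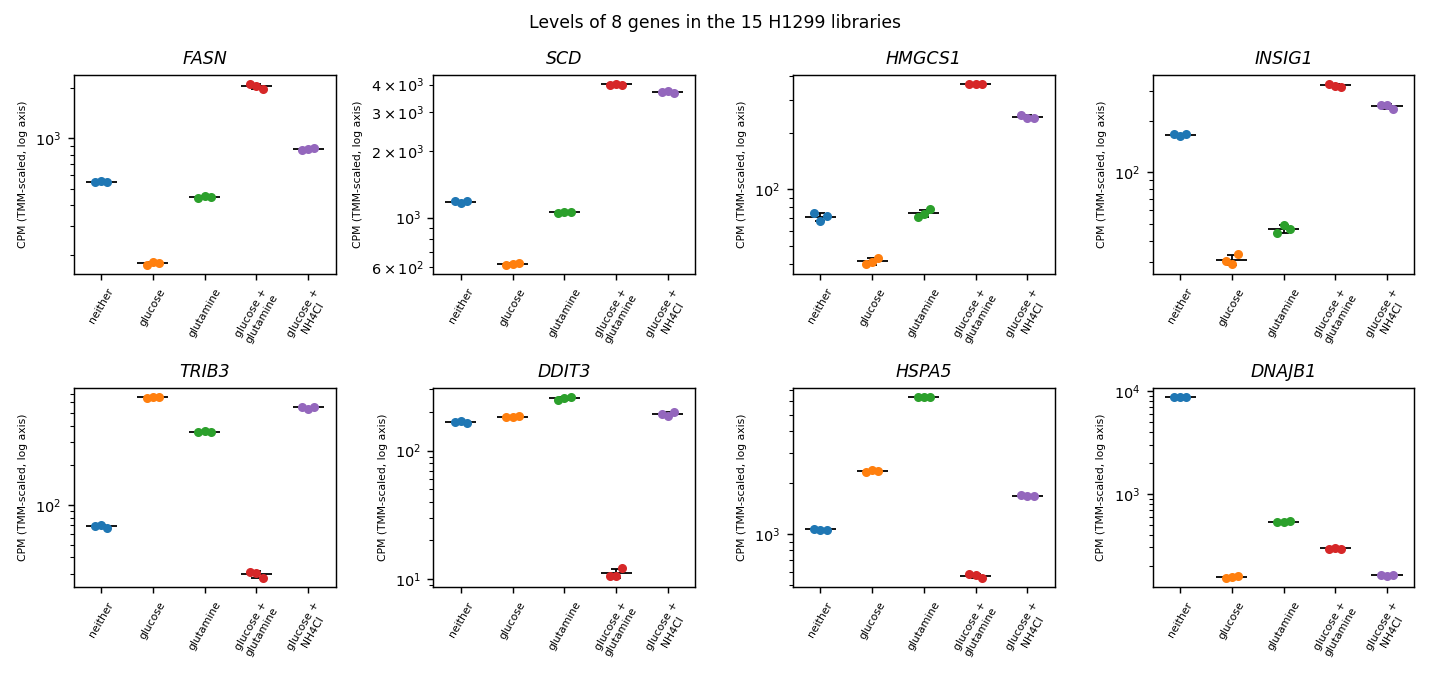
CPM (log axis) of 8 genes in each of the 15 libraries, grouped by medium, with points for libraries, horizontal lines for means and bars for SD (n = 3). FASN was at 179 CPM with glucose, 860 CPM with glucose and NH4Cl and 2060 CPM with glucose and glutamine, while TRIB3 was at 656, 549 and 29.8 CPM in the same media.

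The first comparison asked what glutamine changes in cells that have glucose. Genes of fatty acid and cholesterol synthesis rose, and genes of the ATF4 amino acid response fell. FASN, which encodes fatty acid synthase (ENSG00000169710, chromosome 17, 82078333 to 82098332, GRCh38), rose from 179 ± 3.03 to 2060 ± 69.1 CPM, a log2 change of 3.52 ± 0.021. SCD, the stearoyl-CoA desaturase gene (ENSG00000099194, chromosome 10, 100347124 to 100364834), rose from 618 ± 5.3 to 4010 ± 20.8 CPM. HMGCS1, which encodes the cytosolic HMG-CoA synthase of the cholesterol pathway (ENSG00000112972, chromosome 5, 43289395 to 43313512), rose from 41.2 ± 1.71 to 365 ± 0.687 CPM. TRIB3, a pseudokinase gene induced by ATF4 (ENSG00000101255, chromosome 20, 362835 to 397559), fell from 656 ± 5.1 to 29.8 ± 1.8 CPM, and DDIT3, which encodes the stress transcription factor CHOP (ENSG00000175197, chromosome 12, 57516588 to 57521737), fell from 184 ± 2.2 to 11.1 ± 0.952 CPM.

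With glutamine added to glucose, all 20 measured cholesterol synthesis genes rose, with a median log2 change of 2.25 (camera adjusted p = 1.6e-19), among them IDI1 (log2 3.04 ± 0.034). Of 20 fatty acid synthesis genes 16 rose and 1 fell (median 1.09, adjusted p = 1.82e-09); the gene that fell was MID1IP1 (-1.61), and ACLY, the ATP citrate lyase gene, rose by 1.87 ± 0.026. Of 12 genes of sterol uptake and SREBP feedback 8 rose and 2 fell (median 0.59, adjusted p = 0.00091). INSIG1, whose protein holds the SREBP and SCAP complex in the endoplasmic reticulum, rose by 3.39 ± 0.035. The genes of the SREBP transcription factors also rose, SREBF1 by 1.29 ± 0.03 and SREBF2 by 0.92 ± 0.029. In the ATF4 list 30 of 31 genes fell and ATF5 rose by 0.20, which was not called against a 1.2-fold change (median -2.73, adjusted p = 1.62e-30). SESN2 fell by 4.44 on the log2 scale, as did the cystine transporter gene SLC7A11 (-4.07) and GDF15, a secreted stress cytokine (-5.05), while the ATF4 transcript itself fell by 1.82. ASNS, the asparagine synthetase gene, fell (-3.42), as did its pseudogene ASNSP1 (-4.59), both uncertain because they share sequence.

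The same addition raised 23 of 24 DNA replication genes (median 0.83, adjusted p = 1.19e-13), such as the helicase genes MCM4 (1.88) and MCM2 (1.42). Of 43 nuclear genes of oxidative phosphorylation 38 rose (median 0.37, adjusted p = 3.38e-10), and of 11 cytosolic heat shock genes 10 rose (median 1.61, adjusted p = 4.05e-13). Of 19 immediate early and ERK feedback genes 18 fell (median -0.95, adjusted p = 2.99e-11), such as EGR1 (-3.97) and DUSP6 (-1.53). Of 20 glycolysis genes 18 rose and 2 fell (median 0.42, adjusted p = 3.54e-06), and of 11 interferon response genes 9 rose and 1 fell (median 0.62, adjusted p = 0.00178). Of 20 aminoacyl-tRNA synthetase genes 14 fell and 6 rose (median -1.16, adjusted p = 5.22e-06), a call lost at adjusted p = 0.073 with an estimated correlation. For every list named in these paragraphs on glutamine added to glucose, the counts adjusted over the list alone were equal to those over all genes. By edgeR, 11467 of 16889 genes changed, 5783 higher and 5684 lower, and 2058 of them changed at least 2-fold. Tested against a 1.2-fold change instead of no change, 7417 genes passed.

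**Figure D2:**
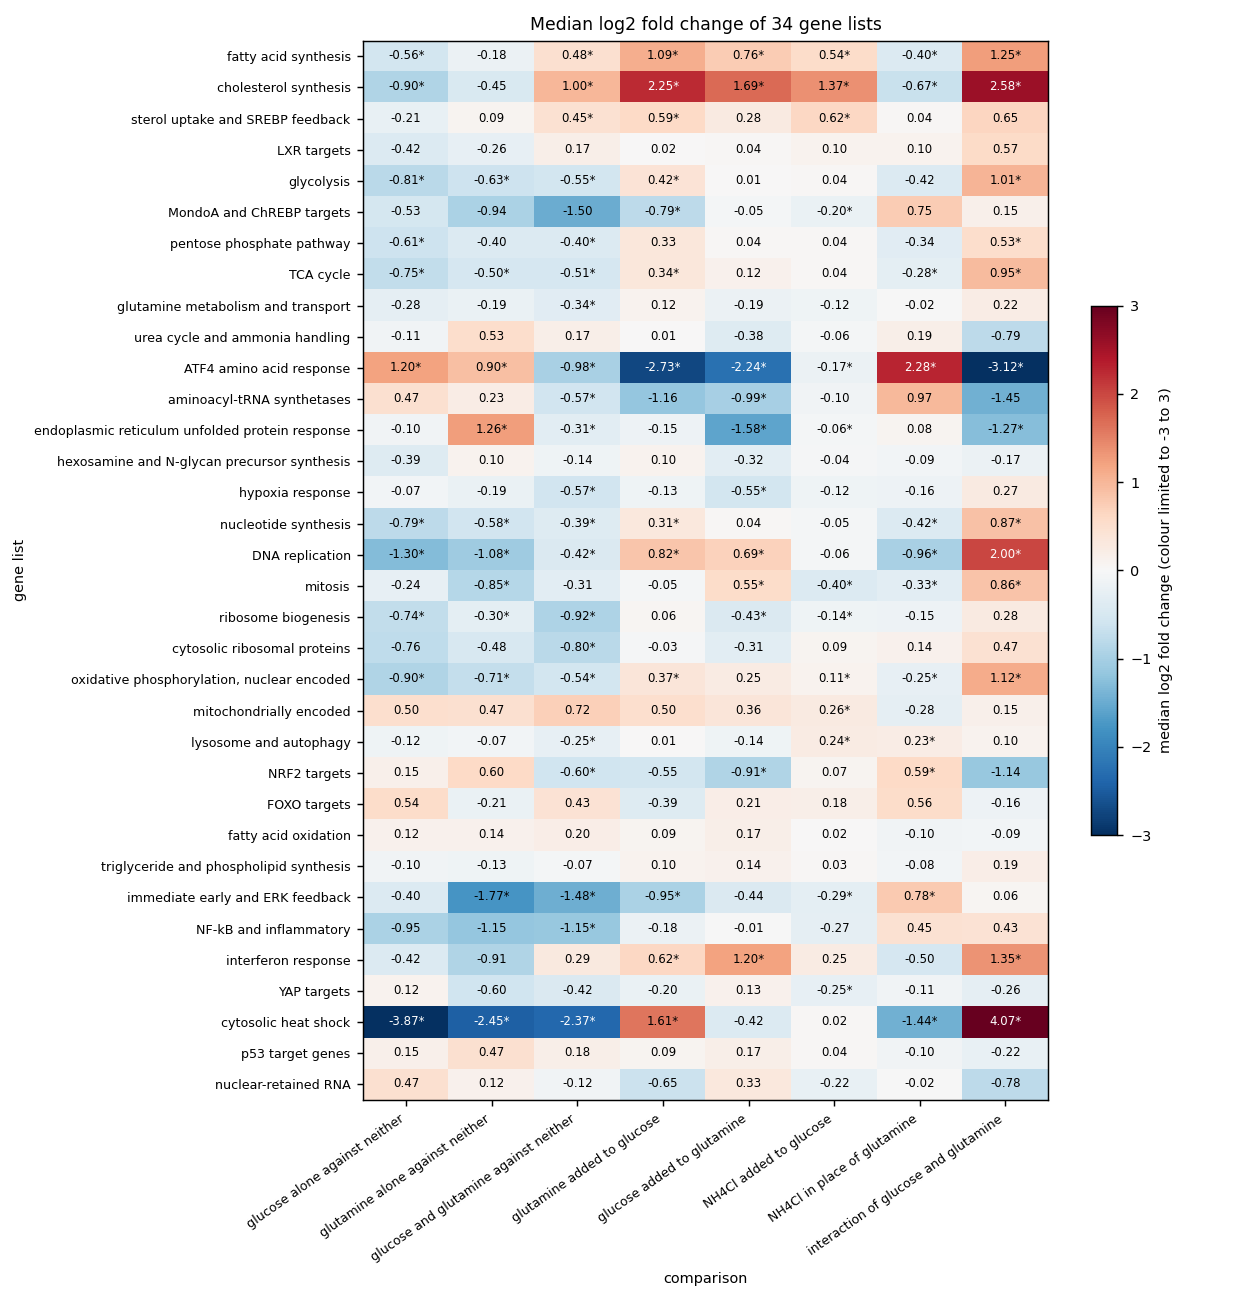
Median log2 fold change (number and colour, colour limited to the range of -3 to 3) of 34 gene lists, one list per line, in each of 8 comparisons. A star marks lists called by camera at an adjusted p under 0.05 with the preset and also with the estimated correlation; under library totals alone the sign turns for negative medians closer to 0 than 0.436, 0.344 and 0.444 in the columns of glucose, glutamine and both against neither, for negative medians closer to 0 than 0.099 with glucose added to glutamine and for positive medians under 0.337 in the interaction, and with DESeq2 size factors for the urea cycle and lysosome lists with glutamine added to glucose.

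The next comparison asked what ammonium changes in cells with glucose and no glutamine. The largest rises included genes of sterol and fatty acid metabolism. INSIG1 (ENSG00000186480, chromosome 7, 155297776 to 155310235) rose from 31 ± 2.11 to 244 ± 7.4 CPM, a log2 change of 2.98 ± 0.036. SCD rose from 618 ± 5.3 to 3700 ± 38.9 CPM (log2 2.58 ± 0.016), HMGCS1 from 41.2 ± 1.71 to 243 ± 4.32 CPM (2.56 ± 0.034) and FASN from 179 ± 3.03 to 860 ± 13.2 CPM (2.27 ± 0.021). LSS, the lanosterol synthase gene, rose by 1.96 ± 0.032. SREBF1 and SREBF2 rose by 1.03 ± 0.03 and 1.02 ± 0.029. RUSC1-AS1, an antisense gene, had a log2 change of 2.20 ± 0.136, which is uncertain because the strand setting of the counting is not given in the sources used here. Among genes with a mean of at least 5 CPM the largest falls were smaller than the largest rises. ARRDC4, a target of the glucose-sensing factor MondoA, fell from 8.91 ± 0.563 to 3.64 ± 0.994 CPM, and KLF10 (-0.82) and DHRS2 (-1.15) fell. DDIT3 did not pass (0.07 ± 0.028, adjusted p = 0.0579), although it did with DESeq2 size factors, library totals alone, the compared media alone and the DESeq2 test (0.08 in each) and without NH4Cl replicate 2 (0.09). TXNIP, another MondoA target, was too low to test, with at most 8 counts in a library.

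With NH4Cl, 19 of 20 cholesterol synthesis genes rose (20 adjusted over the list alone; median 1.37, camera adjusted p = 6.39e-60), and the gene that did not pass over all genes was PMVK (0.14 ± 0.059, adjusted p = 0.0583), which passed with DESeq2 size factors and library totals alone (0.15 in each) and with the compared media alone (0.16). Of 20 fatty acid synthesis genes 16 rose and 2 fell, MID1IP1 and GPAM, with the same counts adjusted over the list alone (median 0.54, adjusted p = 6.66e-25); MID1IP1 did not pass without glucose replicate 2 (-0.10), nor GPAM without glucose replicate 3 (-0.19), and neither was called against a 1.2-fold change. Of 12 genes of sterol uptake and SREBP feedback 8 rose and MBTPS2 fell by 0.16, which was not called against a 1.2-fold change, again the same adjusted over the list alone (median 0.62, adjusted p = 1.13e-18). Of 38 lysosome and autophagy genes 32 rose and 2 fell, the same adjusted over the list alone (median 0.24, adjusted p = 1.1e-17); the sialidase gene NEU1 rose by 0.80 and the Rag GTPase gene RRAGD by 0.67. All 20 mitosis genes fell, also adjusted over the list alone (median -0.40, adjusted p = 1.06e-37), such as MKI67 (-0.54) and AURKA (-0.54). Of 31 ATF4 list genes 20 fell and 4 rose (20 and 6 adjusted over the list alone; median -0.17, adjusted p = 2.05e-09); SLC7A5 (-0.45) and TRIB3 (-0.26, not called against a 1.2-fold change) fell, while GDF15 rose by 0.42 and NUPR1 by 0.87. Of 9 YAP target genes 6 fell, the same adjusted over the list alone (median -0.25, adjusted p = 6.05e-08), led by CCN2 (-0.69). Of 71 cytosolic ribosomal protein genes 59 rose (63 adjusted over the list alone; median 0.09, adjusted p = 4.95e-22), a call lost at adjusted p = 0.075 with an estimated correlation. Of 13 mitochondrially encoded genes 12 rose, and 13 adjusted over the list alone (median 0.26, adjusted p = 7.46e-20, and adjusted p = 0.0144 with an estimated correlation). All genes of the mitochondrial chromosome, listed or not, held 1.058% of counts (SD 0.011) with NH4Cl and 0.856% (SD 0.01) without. By edgeR 4998 genes changed with NH4Cl, 2146 higher and 2852 lower, of which 65 rose and 34 fell at least 2-fold. The count of 2-fold falls was unstable, with 64 without glucose replicate 3, 17 among genes at 1 CPM or more in 3 libraries and 8 with DESeq2, where 47 rose. Against a 1.2-fold change 444 genes passed, and with DESeq2 55 genes passed with at least a 2-fold change.

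Setting the 2 additions side by side asked how far NH4Cl stands in for glutamine. With NH4Cl in place of glutamine, genes of the amino acid response were higher and those of lipid synthesis and DNA replication were lower. TRIB3 was at 549 ± 9 CPM against 29.8 ± 1.8 CPM, DDIT3 at 193 ± 6.54 against 11.1 ± 0.952 CPM, and GDF15 at 50.4 ± 1.81 against 1.14 ± 0.257 CPM (log2 5.47 ± 0.104). FASN was lower, at 860 ± 13.2 against 2060 ± 69.1 CPM (-1.26 ± 0.018). SCD was lower by little (-0.12 ± 0.015), which was not called against a 1.2-fold change.

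Between these media 30 of 31 ATF4 list genes were higher with NH4Cl and ATF5 did not pass (-0.02 ± 0.055, adjusted p = 0.784; list median 2.28, camera adjusted p = 1.15e-35). Of 20 cholesterol synthesis genes 19 were lower (median -0.67, adjusted p = 3.66e-11), and CYP51A1 did not pass (0.07 ± 0.079, adjusted p = 0.451). Of 20 fatty acid synthesis genes 16 were lower and 3 higher (median -0.40, adjusted p = 0.000179). All 24 DNA replication genes (median -0.96, adjusted p = 1.49e-15), such as MCM4 (-1.81), and all 11 cytosolic heat shock genes (median -1.44, adjusted p = 1.24e-15), such as HSP90AA1 (-1.67), were lower. Of 38 lysosome and autophagy genes 27 were higher and 4 lower (median 0.23, adjusted p = 1.27e-06), led by MAP1LC3B (2.30) and SQSTM1 (1.80), which encode autophagy proteins. The counts adjusted over the list alone were the same for these 6 lists. Lower single genes included PRSS23, a secreted serine protease gene (-2.46). By edgeR 10918 genes differed, 5276 higher and 5642 lower, and 6416 passed against a 1.2-fold change.

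Across 16889 genes the log2 changes with glutamine and with NH4Cl had a Pearson r of 0.44 and a Spearman rho of 0.452, with genes not being independent replicates. Both share the 3 glucose libraries, and 20 simulations of unchanged groups against those libraries gave a mean r of 0.50 (0.488 to 0.518) and a mean rho of 0.444. With no changed genes, sharing those libraries by itself fixes r near that value. The simulated r and rho therefore cannot say whether the observed ones are in excess. The covariance was 0.0938 against 0.0149 in the simulations, a difference of 0.079. Calls higher in both numbered 1483 and lower in both 2050, where independent lists would share 735 and 960. The simulations averaged 0.15 and 0.35, but they held no changed genes to call and so set no expectation for these overlaps. Opposite calls numbered 439 and 329, where independent lists would share 977 and 722. The control libraries are too few to split, so part of the excess may come from sharing them.

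**Figure D3:**
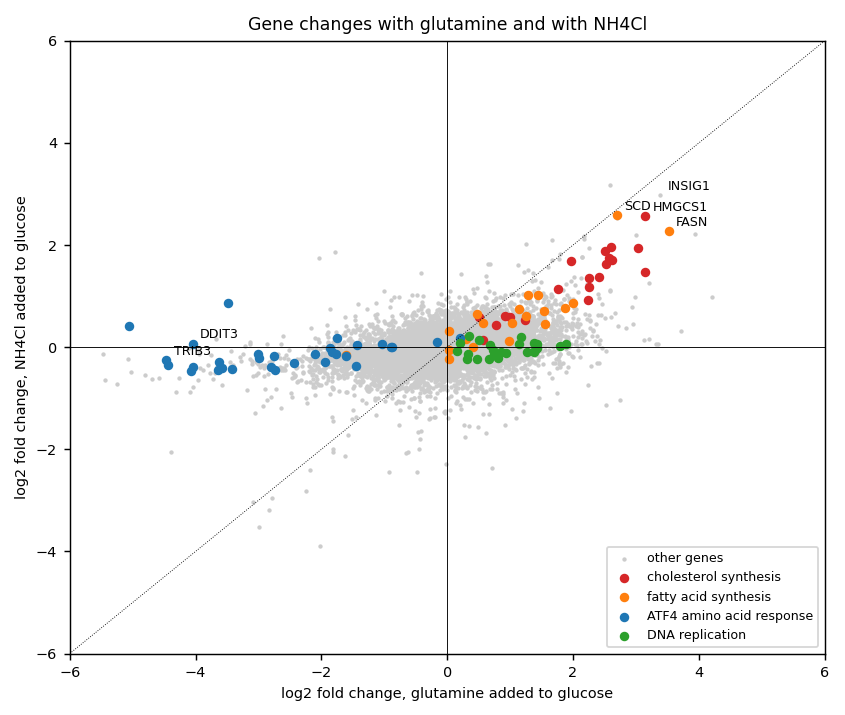
Log2 fold change with NH4Cl added to glucose (vertical axis) against that with glutamine added to glucose (horizontal axis) for 16889 genes, with 4 gene lists coloured and a dotted line of equal change. Cholesterol synthesis genes lie high on both axes (medians 1.37 and 2.25), while ATF4 list genes lie far to the left with little vertical spread (medians -0.17 and -2.73).

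The reverse addition asked what glucose changes in cells that have glutamine. The chaperone gene HSPA5, which encodes BiP (ENSG00000044574, chromosome 9, 125234853 to 125241330), fell from 6350 ± 21.6 to 568 ± 16.1 CPM, a log2 change of -3.48 ± 0.017. HMOX1, the heme oxygenase 1 gene, fell from 622 ± 7.95 to 24.2 ± 1.18 CPM (-4.69 ± 0.032), DDIT3 from 255 ± 7.34 to 11.1 ± 0.952 CPM and ATF3 from 89.1 ± 2.63 to 4.44 ± 0.355 CPM. Genes of sterol synthesis rose, with IDI1, an isoprenoid isomerase gene, going from 37.9 ± 1.27 to 289 ± 0.642 CPM (2.93 ± 0.033) and INSIG1 from 46.9 ± 2.62 to 324 ± 6.43 CPM. FASN rose by 2.21 ± 0.019.

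With glucose added to glutamine, all 25 measured genes of the unfolded protein response of the endoplasmic reticulum fell (median -1.58, camera adjusted p = 1.02e-24), including HSP90B1 (-2.56) and CALR (-1.94), as did 29 of 31 ATF4 list genes while ATF5 rose (median -2.24, adjusted p = 2.64e-31). Of 20 aminoacyl-tRNA synthetase genes 19 fell and HARS1 rose by 0.10, which was not called against a 1.2-fold change or without a low-count filter (median -0.99, adjusted p = 4.06e-16). Of 20 cholesterol synthesis genes 19 rose (median 1.69, adjusted p = 3.71e-19), with CYP51A1 not passing (0.11 ± 0.08, adjusted p = 0.236) except under library totals alone (0.21). Of 20 fatty acid synthesis genes 14 rose and 4 fell (median 0.76, adjusted p = 2.66e-06). Of 20 mitosis genes 19 rose and UBE2C fell, the latter neither under library totals alone nor against a 1.2-fold change (median 0.55, adjusted p = 8.85e-14), led by MKI67 (1.04). The counts adjusted over the list alone were the same for these 6 lists. Of 14 NRF2 target genes 10 fell and 1 rose (10 and 2 adjusted over the list alone; median -0.91, adjusted p = 1.84e-07). Of 71 cytosolic ribosomal protein genes 68 fell, also adjusted over the list alone (median -0.31, adjusted p = 3.12e-26), a call lost at adjusted p = 0.0623 with an estimated correlation. By edgeR 11073 genes changed, 5502 higher and 5571 lower, and 6485 passed against a 1.2-fold change. Scaling by library totals alone moved the median of all genes by 0.099 and the split to 6764 higher and 4359 lower.

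The remaining comparisons set each medium against the one with neither nutrient, which stood apart in composition. In that medium the 10 most counted genes held 12.4% of counts (SD 0.045), against 5.57% (SD 0.044) with glucose, and its TMM factors were 0.793 where the others lay between 1.006 and 1.086. Scaling by library totals alone therefore moved the median of all genes up by 0.436 for glucose, 0.344 for glutamine and 0.444 for both, and a change below that size depends on the scaling. Directions of lists and genes named for these comparisons hold under that scaling unless stated.

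Glucose alone, set against neither, had far less RNA of the cytosolic chaperone genes and more of the ATF4 target genes. DNAJB1, an HSP40 cochaperone gene (ENSG00000132002, chromosome 19, 14514770 to 14529770), was at 154 ± 3.06 CPM with glucose and 8790 ± 43.5 CPM with neither, and HSPA6, an inducible HSP70 gene, at 1.65 ± 0.183 and 2630 ± 58.6 CPM. HSPA1A was at 66.2 ± 2.69 and 25100 ± 519 CPM. Counts of HSPA6 and HSPA1A are uncertain because near-identical copies exist (HSPA7 and HSPA1B) and the handling of reads that map to several places is not given in the sources used here. HSPA7 was under the floor of 3 counts with glucose, so no fold is given. The immediate early gene FOS fell from 1220 ± 2.22 to 15.5 ± 0.72 CPM. SLC7A11 rose from 15.1 ± 1.14 to 279 ± 4.79 CPM (log2 4.21 ± 0.043), and the nuclear RNA NEAT1 rose from 40.2 ± 2.3 to 738 ± 1.68 CPM.

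All 11 cytosolic heat shock genes fell with glucose (median -3.87, camera adjusted p = 1.68e-14), among them HSP90AA1 (-3.59) and HSPA8 (-3.36). Of 31 ATF4 list genes 26 rose and 5 fell (median 1.2, adjusted p = 6.94e-08), with ATF3 (-2.39) and PPP1R15A (-2.95) among those that fell. Of 20 cholesterol synthesis genes 18 fell and TM7SF2 rose (median -0.90, adjusted p = 3.7e-07), with SC5D not passing (0.01 ± 0.065, adjusted p = 0.897) except under library totals alone (0.45), and of 20 fatty acid synthesis genes 16 fell and 3 rose (median -0.56, adjusted p = 0.00101), although under library totals alone 9 fell and 8 rose. FASN (-1.62) and INSIG1 (-2.42) fell. Of 24 DNA replication genes 23 fell (median -1.30, adjusted p = 1.37e-11), such as MCM4 (-2.12), and of 43 oxidative phosphorylation genes 41 fell (median -0.90, adjusted p = 8.69e-15). For these 6 lists the counts adjusted over the list alone were the same. Of 71 cytosolic ribosomal protein genes 70 fell, also adjusted over the list alone (median -0.76, adjusted p = 1.23e-29), a call lost at adjusted p = 0.0531 with an estimated correlation. By edgeR 13136 genes changed, 6735 higher and 6401 lower, and under library totals alone 10145 were higher and 3533 lower.

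Glutamine alone, set against neither, had more RNA of the endoplasmic reticulum chaperone genes and less of the cytosolic ones. HSPA5 rose from 1060 ± 5 to 6350 ± 21.6 CPM (log2 2.58 ± 0.016) and DNAJB1 fell from 8790 ± 43.5 to 535 ± 7.25 CPM (-4.04 ± 0.017). The AP-1 genes JUN (-4.23) and FOS (-4.09) fell, and SLC6A9, a glycine transporter gene, rose by 3.68 ± 0.118. HMGCS1 did not pass (0.06 ± 0.037, adjusted p = 0.136), although it did without replicate 1 of the medium with neither (0.09) and under library totals alone (0.41).

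Of 25 genes of the unfolded protein response 24 rose with glutamine alone (median 1.26, camera adjusted p = 1.16e-14), including HSP90B1 (2.32), HYOU1 (2.13) and SEL1L (2.58); DERL1 fell by 0.11, which was not called against a 1.2-fold change and turned under library totals alone, where 25 genes rose. All 11 cytosolic heat shock genes fell (median -2.45, adjusted p = 1.16e-14), and of 31 ATF4 list genes 26 rose and 5 fell (median 0.90, adjusted p = 2.4e-08), with PCK2 at 2.62. All 20 mitosis genes fell (median -0.85, adjusted p = 7.54e-14), such as AURKA (-1.45), and 23 of 24 DNA replication genes fell while 1 rose (median -1.08, adjusted p = 2.08e-11). Counts adjusted over the list alone were the same for these 5 lists. Of 20 cholesterol synthesis genes 12 fell and 4 rose, the same adjusted over the list alone (median -0.45, adjusted p = 0.00842), a call lost at adjusted p = 0.0772 with an estimated correlation, and under library totals alone 11 fell and 8 rose. Of 20 fatty acid synthesis genes 11 fell and 6 rose, also adjusted over the list alone, and the list was not called (median -0.18, adjusted p = 0.0916); under library totals alone 5 fell and 12 rose. By edgeR 12299 genes changed, 6251 higher and 6048 lower, and under library totals alone 9531 were higher and 3312 lower.

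With both nutrients, set against neither, genes of cholesterol and fatty acid synthesis were higher, and cytosolic heat shock and ATF4 list genes were lower. HMGCS1 rose from 71.3 ± 3.52 to 365 ± 0.687 CPM (log2 2.36 ± 0.032), FASN from 551 ± 4.4 to 2060 ± 69.1 CPM and SCD from 1180 ± 10.5 to 4010 ± 20.8 CPM. FOS fell from 1220 ± 2.22 to 4.37 ± 0.23 CPM and DDIT3 from 166 ± 3.58 to 11.1 ± 0.952 CPM. BMF, a gene of the pro-apoptotic BH3-only family, rose from 0.754 ± 0.231 to 9.54 ± 0.546 CPM.

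Of 20 cholesterol synthesis genes 16 rose and 2 fell (median 1.00, camera adjusted p = 1.12e-09), and under library totals alone 20 rose. Of 20 fatty acid synthesis genes 15 rose and 3 fell (median 0.48, adjusted p = 0.00018). Of 31 ATF4 list genes 25 fell and 3 rose (median -0.98, adjusted p = 2.71e-11), including ATF3 (-5.97) and SLC3A2 (-2.57), and under library totals alone 19 fell and 8 rose. All 20 aminoacyl-tRNA synthetase genes fell (median -0.57, adjusted p = 2.04e-12), of which 15 fell and 4 rose under library totals alone. All 11 cytosolic heat shock genes fell (median -2.37, adjusted p = 6.81e-16). Counts adjusted over the list alone were the same for these 5 lists. All 13 mitochondrially encoded genes rose, also adjusted over the list alone (median 0.72, adjusted p = 2.54e-08), a call lost at adjusted p = 0.0661 with an estimated correlation. All genes of the mitochondrial chromosome, listed or not, held 0.953% of counts (SD 0.015) with both and 0.766% (SD 0.014) with neither. By edgeR 12209 genes changed, 6245 higher and 5964 lower, and under library totals alone 10866 were higher and 2405 lower.

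The last comparison asked whether the effect of glucose differed with and without glutamine. For cholesterol synthesis, glucose lowered IDI1 from 91.3 ± 0.542 to 35.2 ± 0.284 CPM without glutamine and raised it from 37.9 ± 1.27 to 289 ± 0.642 CPM with glutamine, a log2 difference of 4.30. For the amino acid response, glucose raised TRIB3 from 68.9 ± 1.53 to 656 ± 5.1 CPM without glutamine and lowered it from 360 ± 3.99 to 29.8 ± 1.8 CPM with it (-6.85 ± 0.041). The difference was above 0 in 19 of 20 cholesterol synthesis genes (median 2.58, camera adjusted p = 2.06e-13), in 16 of 20 fatty acid synthesis genes, with 3 below 0 (median 1.25, adjusted p = 7.96e-06), and in 23 of 24 DNA replication genes (median 2.00, adjusted p = 1.09e-13). It was below 0 in 29 of 31 ATF4 list genes and above 0 in 2 (median -3.12, adjusted p = 4.39e-20), and below 0 in 24 of 25 genes of the unfolded protein response (median -1.27, adjusted p = 9.91e-12), including HSPA5 (-4.62). Counts adjusted over the list alone were the same for these 5 lists. By edgeR the interaction passed in 12635 genes, 6214 above 0 and 6421 below; under library totals alone the median of all genes moved by -0.337 and the split was 4324 above and 8497 below.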

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

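Tests chosen only after the result was seen were those of background reads and ribosomal RNA, of HSP70 copies, of a few genes taking most of the counts, of deeper sequencing over all libraries and within each medium, and of reads from other libraries. The other kinds of test in this part were chosen beforehand, but the 3 libraries with many low-count genes, to which the test of genomic DNA was applied, were picked from the data.

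The effect of glucose differed with and without glutamine, by the interaction test, in 12635 genes, and 5206 of them were called in opposite directions. Both counts used TMM scaling. Under library totals alone the median of all genes moved by 0.436 for glucose against neither and by 0.099 for glucose added to glutamine. Opposite directions were not counted under that scaling, and genes with small changes could turn. The largest differences above 0 were in the chaperone genes HSPA1A (log2 5.51) and HSPA1B (5.49), near-identical copies whose counts are uncertain, INSIG1 (5.21), DNAJB1 (4.96) and BAG3 (4.54), a cochaperone gene. HSPA7, a near-identical copy of HSPA6, also ranked among them, but it was under the floor of 3 counts with glucose and with both nutrients, so no value is given. The largest below 0 were in GDF15 (-7.52), the glycine transporter gene SLC6A9 (-7.46), SLC7A11 (-7.16), LURAP1L (-7.10), the pseudogene ASNSP1 (-6.92), which shares sequence with ASNS and is uncertain, and TRIB3 (-6.85). A large difference need not be a change of direction. INSIG1 went from -2.42 without glutamine to 2.79 with it. All 11 cytosolic heat shock genes fell without glutamine (median -3.87), and with it 7 fell and 3 rose (median -0.42). DNAJB1 fell there too, from 530 to 544 CPM with glutamine to 291 to 297 CPM with both nutrients.

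Lists called above 0 in the interaction were cytosolic heat shock (median 4.07), cholesterol synthesis (2.58), DNA replication (2.00), interferon response (1.35), fatty acid synthesis (1.25), oxidative phosphorylation (1.12), glycolysis (1.01), the TCA cycle (0.95), nucleotide synthesis (0.87), mitosis (0.86) and the pentose phosphate pathway (0.53). Lists called below 0 were the ATF4 amino acid response (-3.12) and the unfolded protein response (-1.27). The calls of aminoacyl-tRNA synthetases (-1.45, adjusted p = 0.222 with an estimated correlation), NRF2 targets (-1.14, adjusted p = 0.0596), cytosolic ribosomal proteins (0.47, adjusted p = 0.139) and ribosome biogenesis (0.28, adjusted p = 0.0907) were lost with an estimated correlation. Ribosome biogenesis also turned to -0.062 under library totals alone.

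Other ways to split the 12 libraries of the interaction gave fewer genes. In a fit of those libraries the real grouping was the only 1 of 100 splits to reach its own count of 12559, and the highest other split gave 6304. These splits mixed libraries of all the media and so broke up the separate effects of glucose and glutamine too. They therefore cannot exclude chance for the interaction by itself. Pairs of media allow 10 splits each, too few for a share under 0.05. In edgeR fits of each pair the real value and the highest other were 12661 and 0 for glucose against neither, 11891 and 0 for glutamine against neither, 11787 and 0 for both against neither, 11364 and 0 for glutamine added to glucose, 11033 and 0 for glucose added to glutamine, 5002 and 0 for NH4Cl added to glucose and 10793 and 0 for NH4Cl in place of glutamine. At an unadjusted p under 0.05 the highest other splits gave, in that order, 44, 53, 63, 109, 110, 332 and 110 genes.

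Cholesterol synthesis genes were higher with NH4Cl added to glucose. Glucose replicate 2 held 0.151% of its counts in ribosomal RNA genes and glucose replicate 1 many low-count genes, but the lowest NH4Cl library exceeded the highest glucose library by 1.323 in the list's median log2 level, so neither library made the difference. After a trend on GC content and gene length was removed, which explained 2.7% of the variance of the changes, the median was 1.373. These values argue against both technical explanations, and an effect of NH4Cl on these genes remains a hypothesis. Salt and pH had no control medium in this series and stay open.

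Cytosolic heat shock genes were far higher in the medium with neither nutrient than with glucose alone. The 9 members other than the near-identical HSP70 copies had a median log2 change of -3.589 with glucose, and the highest among them was -1.203. Removing the trend on GC content and gene length gave -3.95, and library totals alone gave -3.436. The values for the other members and after removal of the trend argue against shared reads and such a trend as the whole cause. Library totals alone moved the median of all genes by only 0.436. That value therefore could not test whether a few genes taking most of the counts were the cause. A response to the lack of both nutrients remains a hypothesis.

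Replicate 2 of neither, replicate 1 of glucose and replicate 3 of both nutrients held counts for 28337, 35114 and 33716 genes, where the other 12 libraries held 24219 to 26876. At equal depth the lowest of the 3 held 1.04 times as many as the highest of the 12, which left deeper sequencing undecided, but within each medium the lowest ratio was 1.16, beyond that between the other libraries of any medium, which argues against it. Genes seen in 1 library alone were 2.21 times as frequent in the lowest of the 3 as in the highest of the rest, short of the bound set for excluding reads from other libraries of the series. That lowest value was of replicate 2 of neither, with 887 such genes. Replicate 1 of glucose held 2494 and replicate 3 of both nutrients 1938, where the highest of the rest held 402. Over 18677 genes without a count in the other 12 libraries, counts rose with exon length (Spearman rho 0.407, across genes, which are not independent replicates). Genomic DNA is therefore a candidate source, but longer exons can catch more stray reads of any source, so this does not set it apart. No biological explanation was tested, since the 3 libraries come from different media.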

How the results depend on the processing

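The test against a 1.2-fold change and the fit without 3 libraries were chosen after seeing the data. Counts of changed genes stayed within 1.5 times under each alternative except the test against 1.2-fold, stricter by construction, which passed 7417 genes with glutamine added to glucose, 6485 with glucose added to glutamine, 444 with NH4Cl added to glucose and 6416 with NH4Cl in place of glutamine. Among genes changed at least 2-fold, NH4Cl added to glucose gave 99, against 58 by that test and 55 with DESeq2, and both nutrients against neither gave 2839, against 4567 under library totals alone. With the replicate block the count for NH4Cl went from 4998 to 4953, and leaving out single libraries gave 4219 to 4516. Its 34 falls of at least 2-fold became 78 without a low-count filter, 17 with the stricter filter or the compared groups alone, 8 by the test against 1.2-fold or with DESeq2, and 64 without glucose replicate 3. Its falls of any size went from 2852 to 1834 without a filter. Without the 3 libraries that held many low-count genes it was 4440, and elsewhere 12476 (glucose against neither), 11904 (glutamine), 11394 (both), 10595 (glutamine added to glucose), 10551 (glucose added to glutamine), 10449 (NH4Cl in place of glutamine) and 12116 (interaction).

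With an estimated correlation, lists called fell from 20 to 11 for glutamine against neither, 20 to 11 for glucose added to glutamine and 20 to 13 for NH4Cl added to glucose. The interferon list of glutamine against neither (adjusted p = 0.048, lost at adjusted p = 0.124 with an estimated correlation) had 0.0529 with DESeq2 size factors, 0.052 without the 3 libraries and 0.0505 to 0.0571 without single libraries. The YAP list there went from 0.0477 to 0.0541 without replicate 3 of neither, and to adjusted p = 0.188 with an estimated correlation. The pentose phosphate list with NH4Cl went from 0.0402 to 0.0643 without the 3 libraries, 0.0615 without glucose replicate 1 and 0.0666 without NH4Cl replicate 3, and to adjusted p = 0.115 with an estimated correlation. With NH4Cl in place of glutamine it went from 0.0623 to 0.0464 without NH4Cl replicate 3, with adjusted p = 0.163 with an estimated correlation. Nuclear-retained RNA became called in 5 comparisons without the 3 libraries: NH4Cl added (0.164 to 0.00867), NH4Cl in place of glutamine (0.0846 to 0.00965), glutamine added to glucose (0.0861 to 0.0211), glucose added to glutamine (0.217 to 0.0451) and the interaction (0.149 to 0.0454). Leaving out 1 library gave 0.0342 (glucose replicate 1, NH4Cl added), 0.0363 and 0.0463 (glucose replicate 3 and both replicate 3, glutamine added) and 0.0453 (both replicate 3, NH4Cl in place). It had adjusted p = 0.18 to 0.322 with an estimated correlation and medians opposite to the test for NH4Cl added (-0.22), NH4Cl in place (-0.02) and glucose added (0.33). The NF-kB list with NH4Cl went from 0.0759 to 0.0444 without glucose replicate 2 and 0.0258 without NH4Cl replicate 3, with adjusted p = 0.251 with an estimated correlation. The FOXO list with NH4Cl in place of glutamine went from 0.0506 to 0.0464 without replicate 1 of both or NH4Cl replicate 3 and 0.0499 without NH4Cl replicate 2, with adjusted p = 0.0921 with an estimated correlation. The cytosolic ribosomal list with glutamine added to glucose went from 0.0572 to 0.0169 with DESeq2 size factors, 0.0178 without the 3 libraries, 0.0147 without glucose replicate 1 and 0.0407 without replicate 2 of both nutrients, with adjusted p = 0.777 with an estimated correlation. The correlation between both additions was 0.44, and 0.482 without the 3 libraries, with 0.391 to 0.49 over single libraries left out (SD 0.0309); the cause was not tested.

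Of 138 named gene results, 138 kept direction and side of the threshold with the replicate block, 134 with DESeq2 size factors, 135 with the DESeq2 test, 131 under library totals alone and 126 against a 1.2-fold change. Called DERL1, glutamine against neither, turned to 0.23 under library totals alone, whose shift of all genes is larger. Genes that had not passed changed sign. SC5D, glucose against neither, went to -0.011 with DESeq2 size factors, -0.028 without a filter, -0.014 with the DESeq2 test and -0.074 to 0.068 over single libraries left out. ATF5, NH4Cl in place of glutamine, went to 0.003 with DESeq2 size factors, 0.006 with the DESeq2 test and -0.054 to 0.022 over single libraries left out, and CYP51A1 to -0.011 to 0.157 over the same. HARS1 was not called without a filter (0.084). Depth limits genes under the floor of 3 counts.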

Other observations

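The test of a scaled response in this part was chosen only after the result was seen. VEGFA, which encodes an angiogenic growth factor, was at 94.6 ± 2.16 CPM with glucose, 101 ± 1.98 CPM with glutamine, 78.4 ± 2.4 CPM with glucose and NH4Cl and 19.1 ± 1.29 CPM with both nutrients (SD, n = 3). It fell when either nutrient was added to the other, with log2 changes of -2.31 for glutamine and -2.40 for glucose, and fell by 0.27 with NH4Cl, which was not called against a 1.2-fold change. Of 14 hypoxia response genes, to which it belongs, 9 fell and 2 rose with glucose added to glutamine, the same adjusted over the list alone (median -0.55, camera adjusted p = 0.00598). With glutamine added to glucose 7 fell and 5 rose, also adjusted over the list alone, and the list was not called (median -0.13, adjusted p = 0.254).

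NEAT1, a long RNA retained in the nucleus, was at 738 ± 1.68 CPM with glucose, 908 ± 11 CPM with glucose and NH4Cl (not called against a 1.2-fold change), 291 ± 2.65 CPM with glutamine and 218 ± 3.05 CPM with both. The death receptor gene TNFRSF10B fell from 237 ± 7.64 to 59.6 ± 1.83 CPM with glutamine added to glucose and was at 218 ± 2.29 CPM with NH4Cl, not called against a 1.2-fold change, while the p53 target list that holds it was not called (camera adjusted p = 0.81), its median of 0.085 differing in sign from its mean of -0.116 and from the test. CCNG2, a cyclin G2 gene and FOXO target, fell by 0.72 on the log2 scale with glutamine added to glucose and was higher by 0.92 with NH4Cl than with glutamine. The FOXO list was called in neither comparison. With glutamine added to glucose 5 of its 10 genes fell (median -0.39, camera adjusted p = 0.211), and with NH4Cl in place of glutamine it had camera adjusted p = 0.0506. Of 5 targets of MondoA and ChREBP 4 fell with glutamine added to glucose (4 fell and 1 rose adjusted over the list alone; median -0.79, camera adjusted p = 0.00683), led by ARRDC4, which went from 8.91 ± 0.563 to 1.06 ± 0.28 CPM.

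A hypothesis was that NH4Cl gives the glutamine response at a single smaller scale. The ratio of the median change with NH4Cl to that with glutamine was 0.609 for cholesterol synthesis genes and 0.064 for ATF4 list genes. The difference of 0.545 (SD 0.066 over 2000 resamples of the genes, which are not independent replicates) argues against a common scale for these lists. That SD does not measure the spread between libraries. A candidate explanation left open is that ammonium reaches the sterol genes apart from the amino acid response, which no sample here tests.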
